A study of Homo sapiens with 4 samples.

How the data were processed

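RNA was measured in MCF-7 cells, an established human breast cancer line, in 4 groups of 1 library each. Cells carried the shRNA labelled shNS, taken here as the control, or the shRNA labelled shSETD1A, delivered by lentivirus. Each was sampled without and with estrogen (E2). Per the labels' protocols, cells were grown in DMEM with serum, total RNA was isolated with a column kit and libraries were made with a stranded mRNA kit. Doses, times and culture conditions during E2 treatment are not given in the sources used here.

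The deposited table held 24331 rows, each with a gene symbol, an assembled-locus identifier and 1 value per library. The values were read as FPKM made by the authors (fragments scaled by gene length and by mapped fragments per library). The file did not name its unit. It was inferred from Cufflinks, which is named with TopHat2 2.0.12, Bowtie2 2.2.3 and the hg19 build in the submitters' processing notes, and from values with decimals whose column sums differed between libraries. The Cufflinks version, the gene annotation, the use of strand in counting and the scaling between libraries are not given in the sources used here. FPKM divides by gene length, so a few fragments on a very short gene give a very large value. Fragments shared by near-identical genes may have been split or assigned to one of them. This concerns ribosomal proteins, histones, actins, HLA genes, CEACAM5 and CEACAM6, the AKR1C genes and the IFITM genes, whose values are uncertain to that extent.

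The table held no counts. Relative depth was approximated from the lowest steps of values at 442 olfactory receptor genes, which have similar coding lengths in the GENCODE 29 annotation. The median value at a step taken as 1 fragment was 0.0595, 0.069, 0.059 and 0.068 FPKM in shNS without E2, shNS with E2, shSETD1A without E2 and shSETD1A with E2. These medians came from 10, 7, 12 and 7 genes. The step was sought only between 0.045 and 0.08 FPKM, so no median could lie outside that window. A gene of that length therefore had about 16.8, 14.5, 16.9 and 14.7 fragments per FPKM. The total depth of each library is unknown.

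Differences were computed on the scale log2(FPKM + 1), so a fold change understates the difference of a gene with low values. Genes with a mean of at least 1 FPKM over the 4 libraries were compared (12127 rows). A gene was called higher or lower at a difference of at least 2-fold. There were 5 comparisons: E2 against no E2 in shNS and in shSETD1A, shSETD1A against shNS without and with E2, and the difference of the E2 differences. With 1 library per group, a comparison of 2 libraries allows no test, and no difference has a replicate check. An additive fit of shRNA and E2 over the 4 libraries, which would take the difference of the E2 differences as its error, was not run. No p-value, standard error or standard deviation between replicates is given, and all calls describe these libraries, not the conditions.

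Before the data were examined, 22 gene lists, the comparisons, the alternatives and the rule for naming genes were fixed. A list was described by the median difference of its measured members. Some lists are wider than their names. The luminal regulators also hold the keratins KRT8, KRT18 and KRT19 and the cadherin CDH1. The matrix metalloproteinase genes also hold the inhibitor genes TIMP1, TIMP2 and TIMP3. The SET1 and MLL complex genes also hold the H3K4 demethylases KDM1A, KDM5A, KDM5B and KDM5C. That median was placed among 10000 random lists of the same size, matched on mean level in 10 bins. The rule named SETD1A and 8 other genes (ESR1, TFF1, GREB1, PGR, CCND1, MYC, MKI67 and CDKN1A). It also named the 8 highest and 8 lowest genes of each comparison among those with a mean of at least 5 FPKM, and the 5 highest and 5 lowest genes past 2-fold the same way in comparisons that share no library. Up to 4 members of each list with the largest difference completed it. Over the 5 comparisons, 79 of the 80 places at the ends went to rows of small RNA genes such as miRNAs and snoRNAs, some of them repeatedly. The same rule was therefore also applied without those 1679 rows, 94 of which had a mean of at least 1 FPKM. That step, and the count of calls without small RNA rows, were chosen after seeing the data. A few further genes are named to complete counts of 5 or fewer, or for what they encode, and were chosen after their values were seen. They are CDC45, CRABP2, DEFB126, ELOVL2, FOXA1, GATA3, HERC5, HIF1A, IFITM1, IRF7, IRF9, KLF4, KRT8, KRT18, LIPH, MT1F, PRSS23, STAT1, STAT2 and TXNIP, and the members of groups added in the closing part.

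Of the rows, 405 carried several symbols, so a value there is shared by overlapping genes. Symbols on more than 1 row (400 symbols) were read from the row with the highest mean. Of all rows, 96.2% carried a symbol found in the RefSeq gene table. The list of mitochondrially encoded genes matched 0 rows and is not described. The reference annotation used here is for another build than hg19, so no coordinates are given. It served for olfactory receptor lengths, the SETD1A transcript length and overlaps of small RNA genes with longer genes. Another 100 rows were left unnamed.

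Alternatives were a pseudocount of 0.1 or 5, no filter or a mean of at least 5 FPKM, and scaling by median of ratios or by upper quartile. The steps were tested on simulated data for the E2 comparison in shNS, with 12060 genes and noise of 0.20 (SD, log2). This noise was set, not estimated, since the libraries have no replicates, and it was the same at all levels. Small RNA rows were left out of the simulation. The shares that follow hold for that setting and are not error rates of the real comparisons. Of 50 genes made 3-fold higher, 94.0% were called, and of 50 made 6-fold higher, 100% were. Of 50 made 1.5-fold higher, 6.0% were called, and of 50 made 3-fold lower, 78.0%. Of 11861 genes left alone, 1 was called. A list of 30 with 20 genes 1.5-fold higher lay above all its random lists, and 4.5% of 200 lists of unaltered genes lay outside the central 95%. Noise was drawn separately for each gene and those 200 lists were random genes. The share therefore does not show how often a list whose members vary together leaves that range. Members of the fixed lists may vary together, so a place above or below all random lists is a description and not a test. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.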

Results

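The transcriptome of MCF-7 cells, an estrogen receptor-positive breast cancer line, was profiled in 4 libraries. The groups crossed an shRNA (shNS or shSETD1A) with estrogen (E2) treatment, and each group was 1 library. SETD1A encodes a histone H3 lysine 4 methyltransferase, the catalytic subunit of a SET1 complex. The comparisons ask which genes differed with E2, which differed between the shRNAs, and whether the E2 difference was of another size under shSETD1A. The libraries were alike in breadth: 12008, 11987, 11931 and 11951 rows reached 1 FPKM in shNS without E2, shNS with E2, shSETD1A without E2 and shSETD1A with E2. The 10 highest rows held 7.67%, 7.82%, 9.53% and 9.91% of the summed FPKM in that order. All values below come from single libraries without replicates.

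SETD1A, the targeted gene, was not lower in the libraries labelled shSETD1A. It stood at 13.9 FPKM in shNS without E2 and 12.99 FPKM in shNS with E2, against 16.3 and 17.6 FPKM in the libraries labelled shSETD1A without and with E2. The ratio of shSETD1A to shNS was 1.17 without E2 and 1.35 with E2. From the approximate depth, about 1590, 1298, 1903 and 1746 fragments lay behind these values, a counting error of 2.29% to 2.78%. The log2 differences of 0.21 and 0.41 exceeded their approximate 95% counting half-widths of 0.10 in both cases. Such half-widths cover counting only and hold no spread between cultures. The 2 differences did not stand out among 2559 genes of like level, where they lay at percentiles 72.6 and 82.4. No genome or annotation of the authors' build was used, so the part of SETD1A that the shRNA targets was not looked at. Because SETD1A goes against the label, the arm is called "the library labelled shSETD1A", and no direction given for it can be read as an effect of less SETD1A mRNA. Of the 22 measured SET1 and MLL complex genes, SETD1A included, none differed 2-fold, and 13 were above 0 without and 15 with E2. Their medians were 0.09 without E2 (percentile 87.6) and 0.32 with E2 (percentile 99.6, outside the central 95% of random lists). MLL (0.67) and KDM1A (0.66), an H3K4 demethylase, differed most with E2. KDM6A, an H3K27 demethylase of MLL complexes, was lower (log2 differences -0.90 and -0.56, FPKM 18.8 and 14.2 in shNS, 9.63 and 9.30 in shSETD1A).

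**Figure D1:**
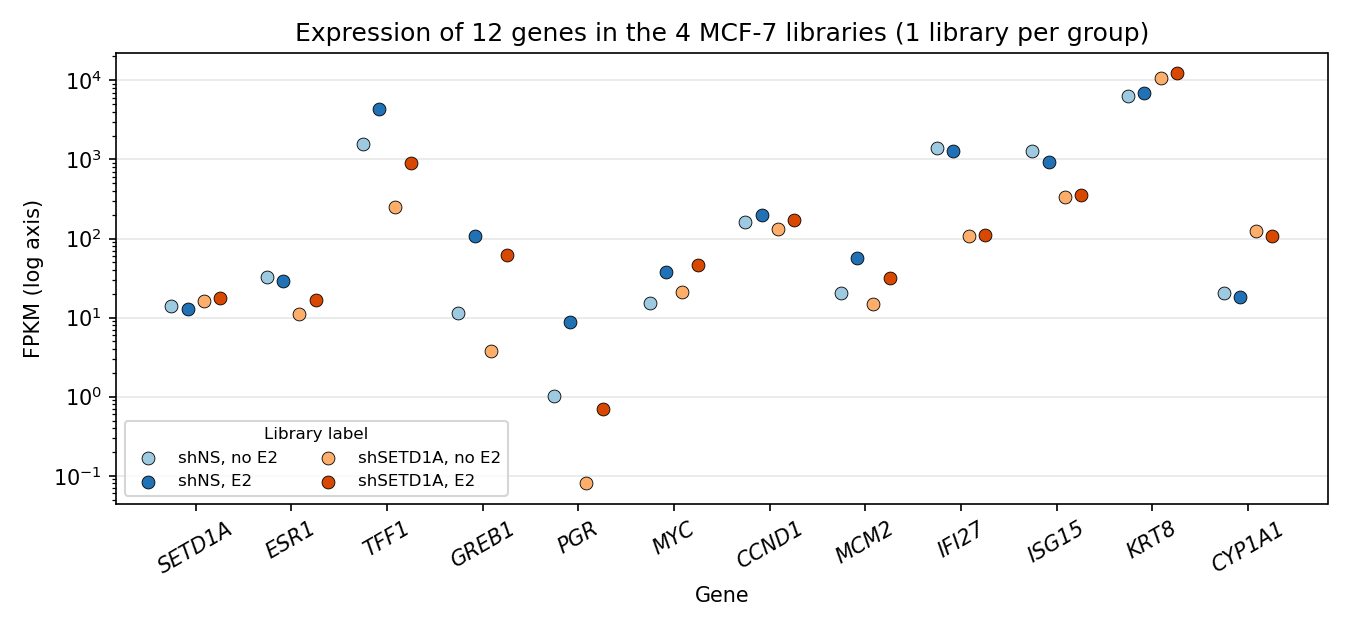
FPKM (log axis) of 12 genes in the 4 libraries; each point is 1 library, coloured by its label. SETD1A lies at 13.9 and 12.99 FPKM in shNS and at 16.3 and 17.6 FPKM in the libraries labelled shSETD1A, TFF1 and GREB1 are higher with E2 under both shRNAs, and IFI27 is near 1405 and 1291 FPKM in shNS but 109 and 112 FPKM in shSETD1A.

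In the shNS libraries, E2 went with higher levels of estrogen target genes, of DNA replication genes and of mitotic genes. GREB1, an estrogen receptor cofactor, was 8.78-fold higher with E2 (11.3 to 107 FPKM). PGR, the progesterone receptor, was 4.87-fold higher, TFF1, a secreted trefoil peptide, was 2.75-fold higher, and MYC was 2.37-fold higher. CCND1 (cyclin D1) differed by 1.25-fold. ESR1, which encodes estrogen receptor alpha, stood at 32.9 FPKM without and 28.7 FPKM with E2. Of the 61 measured genes of the E2-induced list, 31 were at least 2-fold higher, 30 lay between the bounds and 0 were 2-fold lower. The list's median of 1.02 was above all 10000 random lists. Its largest members were KRT13 (3.60), GREB1 (3.13), CXCL12 (2.83), a chemokine, and MYBL1 (2.80). Of the 32 E2-repressed genes, 6 were 2-fold lower (PSCA, IL1R1, BCAS1, ID1, BMF and LIPH) and 1 was 2-fold higher (SEMA3B, 1.03). Their median of -0.60 was below all random lists. PSCA, a cell surface antigen, stood at 165 FPKM without and 40.0 FPKM with E2.

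All 47 DNA replication genes were above 0 in shNS, 29 of them at least 2-fold, with a median of 1.11 that was above all random lists. DSCC1 (1.92), MCM10 (1.82), CCNE2 (1.75), which encodes cyclin E2, and UHRF1 (1.62) were the highest. The 39 mitotic genes were also all above 0, with a median of 0.70. Of these, MAD2L1 (1.55), CDK1 (1.06) and NCAPG (1.02) passed 2-fold, and MKI67, a proliferation marker, was higher by 0.58. Ribosome biogenesis genes had a median of 0.45, with 31 of 32 above 0 and none past 2-fold; FBL (0.77) and NOP58 (0.75) led. Ribosomal protein genes had a median of 0.19, also above all random lists. Replication-dependent histone genes, whose mRNAs mostly lack a poly(A) tail, had a median of -0.36 with 2 of 21 above 0, below all random lists. CDKN1A, the p21 cell cycle inhibitor, stood at 210 FPKM without and 144 FPKM with E2.

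Smaller shifts in shNS were seen in immediate early genes (median -0.25, percentile 0.05, JUNB at -0.98), interferon-induced genes (-0.22, percentile 0.02) and luminal transcription regulators (-0.24, percentile 0.03, with NRIP1 higher by 1.08). Mesenchymal markers (median -0.35, percentile 0.22, 9 genes) and matrix metalloproteinase genes (-0.31, percentile 0.57, 9 genes) were also low. The median was -0.17 for SET1 and MLL complex genes (percentile 2.81) and -0.11 for p53 targets (percentile 7.58). It was -0.01 for unfolded protein genes (percentile 60.6), -0.05 for hypoxia genes (percentile 32.8) and 0.09 for cholesterol synthesis genes (percentile 97.0). It was 0.07 for oxidative phosphorylation genes (percentile 94.0), 0.08 for basal markers (percentile 85.8), -0.07 for leukocyte markers (percentile 31.8) and 0.02 for housekeeping genes (percentile 74.8). Outside the lists, SFXN2 (2.64), NPY1R (2.61), a neuropeptide Y receptor, and C5AR2 (2.10) were among the highest, while VTCN1 (-1.60), C2orf54 (-1.43), GRHL3 (-1.36), ACHE (-1.36), ITGB6 (-1.35) and KIAA0513 (-1.32) were among the lowest. PKIB of the E2-induced list was at 2.28. UBA7 (3.18) ranked high through 1 library, which read 43.6 FPKM while the other 3 read 3.91 or less. In total 195 rows were higher and 64 lower, and 170 and 42 without small RNA rows.

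In the libraries labelled shSETD1A, where SETD1A was not lower, E2 again went with higher medians of estrogen target, DNA replication, mitotic and ribosome biogenesis genes and a lower median of E2-repressed genes. GREB1 stood at 3.81 FPKM without and 61.5 FPKM with E2, TFF1 was 3.59-fold higher (249 to 897 FPKM) and MYC 2.11-fold higher. PGR differed by 0.66 on the log2 scale, at 0.080 and 0.701 FPKM, and ESR1 was 1.48-fold higher (11.016 to 16.8 FPKM). CCND1 was 1.29-fold and MKI67 1.36-fold higher, and CDKN1A stood at 192 and 184 FPKM. Of the 61 E2-induced genes, 20 were at least 2-fold higher and 0 were 2-fold lower, with a median of 0.68, above all random lists. GREB1 (3.70), CA12 (2.32), CALCR (2.31), the calcitonin receptor, and MYB (2.26) led. The 32 E2-repressed genes had a median of -0.27, below all random lists, and none was 2-fold lower; IL1R1 (-0.93) and PSCA (-0.64) were the lowest. All 47 DNA replication genes were above 0 with a median of 0.66, and 5 of them passed 2-fold (GINS2, UHRF1, CDC6, MCM2 and CDC45). The mitotic median was 0.27 with 35 of 39 above 0, and the ribosome biogenesis median was 0.40 with 31 of 32 above 0. All 3 medians lay above all random lists, and all 42 ribosomal protein genes were above 0 (median 0.15, percentile 99.99).

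The other lists lay within 0.16 of 0 in this comparison. Medians were 0.10 for unfolded protein genes (percentile 98.9), -0.07 for p53 targets (percentile 2.11), 0.10 for oxidative phosphorylation genes (percentile 97.4) and 0.08 for cholesterol synthesis genes (percentile 95.5). They were -0.13 for matrix metalloproteinase genes (percentile 4.85), 0.16 for leukocyte markers (percentile 94.4), -0.05 for immediate early genes (percentile 12.7) and 0.04 for basal markers (percentile 74.0). SET1 and MLL complex genes (0.02), luminal regulators (0.02), hypoxia genes (0.02), housekeeping genes (0.06), histone genes (0.00), mesenchymal markers (-0.02) and interferon-induced genes (-0.01) were inside the central 95% of their random lists. Beyond the lists, NPY1R (2.35), KLK12 (2.05), SULF1 (1.94) and DEPTOR, an inhibitor of mTOR kinase (8.39 to 35.4 FPKM), were high. VTCN1 (-0.95), LYRM5 (-0.87), HIF1A-AS2 (-0.77), ST8SIA4 (-0.75), CSTA (-0.73) and ACHE (-0.72) were low. CELSR3 (6.18) read 365 FPKM in this E2 library and at most 4.23 FPKM in the other 3, and TIGD1 (-3.40) read 84.1 FPKM without E2 and at most 7.06 FPKM elsewhere. In total 84 rows were higher and 25 lower. Without small RNA rows these were 54 and 4, the 4 being TIGD1, MME, MT1F and DEFB126, the last of which was listed at 0 with E2.

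E2 differences were nearer 0 in the libraries labelled shSETD1A, in which SETD1A was not lower, for 67.2% of all genes other than small RNA rows, and the SD across these genes was 0.36 in shNS and 0.24 in shSETD1A. Of the lists, this held for 39 of 61 E2-induced genes, 29 of 32 E2-repressed genes, 37 of 39 mitotic genes and 46 of 47 DNA replication genes, so the share of the E2-induced genes (63.9%) was not above that of all genes. The medians of the difference between the E2 differences were -0.24, 0.31, -0.39 and -0.41 in that order. The random lists were matched on mean level and not on the size of the E2 difference in shNS, so a list's place among them is not read as a result here. The ratio of the E2-induced medians was 0.668. Among the E2-induced genes KRT13 (-2.62), CXCL12 (-1.73) and PKIB (-1.13) had smaller E2 differences in the library labelled shSETD1A. CXCL12 was already higher there without E2 (30.1 FPKM, and 65.7 FPKM with E2) than in shNS (2.95 and 27.2 FPKM). CA12 (1.35), a carbonic anhydrase, and SYBU (1.01) had higher ones. For PGR (-1.63) and MYBL1 (-1.08) the value comes wholly or in part from adding 1 before the log2, because in shSETD1A PGR stood at 0.080 and 0.701 FPKM and MYBL1 at 0.397 and 3.59 FPKM. Among replication genes DSCC1 (-1.22), MCM10 (-1.05) and CCNE2 (-1.02) differed most. Part of the MCM10 value also comes from adding 1, as MCM10 stood at 1.02 and 2.45 FPKM in shSETD1A. Among mitotic genes MAD2L1 (-1.13) and HMMR (-1.01) differed most. TFF1 (0.39) and GREB1 (0.56) went the other way, as did ESR1 (0.76). MYC (-0.16), CCND1 (0.05), MKI67 (-0.14) and CDKN1A (0.48) are given as values.

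Outside these lists, PTGES (-1.81), STC1 (-1.69) and SFXN2 (-1.42) had lower E2 differences in the library labelled shSETD1A than in shNS, and KLK12 (1.40), C4orf48 (1.31), GLI4 (1.03) and P2RY6 (1.03) higher ones. PSCA (1.38) had a smaller decrease with E2 in the library labelled shSETD1A. It stood there at 35.3 FPKM without and 22.3 FPKM with E2, against 165 and 40.0 FPKM in shNS. HIF1A-AS2 (-2.87), TIGD1 (-3.71), UBA7 (-3.39) and CELSR3 (6.38) were at the ends, the last 3 through 1 library each. HIF1A-AS2 also owed most of its value to 1 library, at 23.7 FPKM in shNS with E2 and at most 5.62 FPKM elsewhere. Histone genes had a median of 0.36 (20 of 21 above 0; HIST4H4 at 1.32 and HIST1H2BO at 1.19), and interferon-induced genes one of 0.19. Medians were 0.20 for SET1 and MLL complex genes, 0.19 for luminal regulators, 0.19 for immediate early genes, -0.09 for ribosome biogenesis genes and -0.04 for ribosomal protein genes. The other 10 measured lists had medians inside the central 95% of these random lists, a place that is likewise not read as a result. In all, 62 rows were higher and 89 lower, and without small RNA rows 21 and 56.

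**Figure D2:**
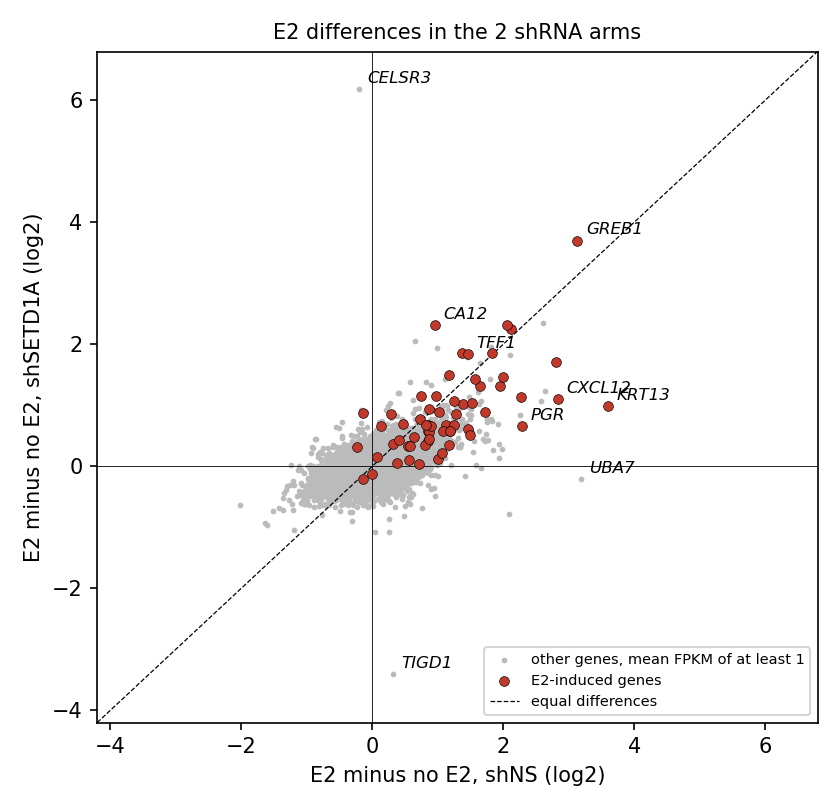
E2 minus no E2 (log2 of FPKM + 1) in shNS (x axis) against shSETD1A (y axis), 1 point per gene other than small RNA rows; red points are the 61 measured E2-induced genes and the dashed line marks equal differences. The list's median is 1.02 in shNS and 0.68 in the libraries labelled shSETD1A, and CELSR3, TIGD1 and UBA7 lie apart through 1 library each.

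Without E2, interferon-induced genes were lower in the library labelled shSETD1A than in shNS, as were estrogen target genes as a list, while ribosomal protein genes were higher; SETD1A itself was not lower. All 38 measured interferon-induced genes were below 0 and 31 were at least 2-fold lower. Their median of -1.99 (3.96-fold lower) was below all random lists. IFI27 (-3.68) stood at 1405 FPKM in shNS and 109 FPKM in shSETD1A. XAF1 (-3.35), CMPK2 (-3.25) and IFI44L (-3.11) followed. IFITM1, an antiviral membrane protein, was at 590 and 140 FPKM, while STAT1 (-0.65) and IRF9 (-0.25), which carry the interferon signal, did not pass 2-fold. Of the 5 measured leukocyte markers, LCP1 (-3.32), CD74 (-2.13) and HLA-DRA (-1.80) were 2-fold lower, for a median of -1.80 below all random lists. LCP1 encodes an actin-bundling protein, and CD74 and HLA-DRA encode parts of the MHC class II pathway.

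Estrogen target genes had a median of -0.33 without E2, below all random lists, with 19 of 61 at least 2-fold lower and 3 higher (CXCL12, WISP2 and PRSS23). ASCL1 (-4.11), a neuroendocrine transcription factor, and RET (-3.33), a receptor tyrosine kinase, were the lowest. TFF1 was 6.23-fold lower (1557 and 249 FPKM), ESR1 2.82-fold (32.9 and 11.016 FPKM) and GREB1 2.55-fold. PGR was 1.88-fold lower on this scale (1.02 and 0.08 FPKM). CCND1 (-0.28), MYC (0.43), MKI67 (-0.77) and CDKN1A (-0.13) did not pass 2-fold. E2-repressed genes had a median of 0.30, above all random lists; CYP1A1 (2.54), a dioxin-inducible P450, was higher and PSCA (-2.19) lower. Luminal regulators had a median of 0.06 (percentile 84.5) but a mean of -0.18, since XBP1 (-2.76), ESR1 (-1.50), AR (-1.48), SPDEF (-1.07) and KLF4 were 2-fold lower. FOXA1 (-0.76) was lower too, and GATA3 stood at 425 and 505 FPKM. The simple epithelial keratins KRT8 (6266 and 10646 FPKM) and KRT18 (3728 and 6234 FPKM), which are members of that list too, were higher.

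Mitotic genes (median -0.42, 3 of 39 above 0, below all random lists) and DNA replication genes (median -0.31, percentile 0.01, with GINS2 at -1.73, CCNE1 at -1.04 and MCM10 at -1.02) were lower as lists in the library labelled shSETD1A without E2. At least 2-fold lower were 0 of 39 mitotic genes and 3 of 47 replication genes. Ribosomal protein genes were higher, with a median of 0.55 and 41 of 42 above 0, above all random lists; RPL11 (1.13) and RPS8 (1.09) passed 2-fold. Basal epithelial markers had a median of 0.40 (percentile 99.99), with CAV1 (1.24), ANXA1 (1.24) and CAV2 (1.02) higher and KRT15 (-1.03) lower. Mesenchymal markers had a median of -0.47 (percentile 0.59). In that list TAGLN (-1.86), VIM (-1.77), ACTA2 (-1.74) and COL6A1 (-1.14) were 2-fold lower and COL5A1 (1.90) higher. Histone genes had a median of -0.58, below all random lists, and unfolded protein genes one of -0.32 (percentile 0.11). Within the latter DDIT4 (1.52) and PHGDH (1.37), a serine synthesis enzyme, were higher and HERPUD1 (-1.07) lower. p53 targets had a median of 0.24 (percentile 99.9; BTG2 at 1.52, ZMAT3 at 1.14 and ACER2 at -1.37). Immediate early genes had a median of 0.17 (percentile 97.8) but a mean of -0.02, with CTGF (1.73) higher and KLF2 (-1.51) and NR4A1 (-1.49) lower.

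Medians of the remaining lists without E2 were 0.10 for ribosome biogenesis (percentile 94.2), -0.11 for oxidative phosphorylation (percentile 26.0), 0.03 for hypoxia (percentile 69.4) and -0.03 for cholesterol synthesis (percentile 57.9). They were -0.22 for matrix metalloproteinase genes (percentile 8.98; MMP9 at 1.15, MMP16 at -1.31 and TIMP2 at -1.10) and -0.09 for housekeeping genes (percentile 34.3; B2M at -1.46 and EEF1A1 at 1.05). The lowest genes outside the lists, with a mean of at least 5 FPKM, included FXYD4 (-5.77), an ion transport regulator, CEACAM5 (-4.43), a carcinoembryonic antigen, ACTG2 (-3.85), ENTPD8 (-3.81) and CXCL17 (-3.75). CXorf61 stood at 25.1 FPKM in shNS and was listed at 0 in shSETD1A. KRT4 (4.16), WNT6 (3.95), GABRP (3.29), BTG3 (3.11), AKR1C2 (2.98) and CDC42EP3 (2.96) were the highest of such genes, apart from TIGD1 (4.11), which rests on its single high library. In all, 330 rows were higher and 558 lower, and 303 and 535 without small RNA rows.

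With E2, interferon-induced, estrogen target and proliferation genes were lower as lists in the library labelled shSETD1A than in shNS, and ribosomal protein genes were higher; SETD1A was again not lower. Of the 38 interferon-induced genes, 30 were at least 2-fold lower and 1 (HERC5, 0.05) was above 0. Their median was -1.72 (3.29-fold lower), below all random lists. IFI27 (-3.51), IFI44 (-3.38), XAF1 (-3.27) and IFI44L (-3.24) were the lowest. LCP1 (-3.04), HLA-DRA (-2.15) and CD74 (-1.84) were again 2-fold lower among the 5 leukocyte markers (median -1.84, below all random lists). E2-induced genes had a median of -0.80, below all random lists, with 25 of 61 at least 2-fold lower and 3 higher (WISP2 at 2.62, CXCL12 at 1.24 and ELOVL2 at 1.08). ASCL1 (-4.32), RET (-3.46) and PGR (-2.54) were the lowest of them. TFF1 was 4.77-fold lower (4280 and 897 FPKM), GREB1 1.73-fold (107 and 61.5 FPKM) and ESR1 1.67-fold (28.7 and 16.8 FPKM). CCND1 (-0.23), MYC (0.27), MKI67 (-0.92) and CDKN1A (0.35) did not pass 2-fold.

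Proliferation genes were lower in the library labelled shSETD1A with E2: the medians were -0.85 for mitotic genes, none of 39 being above 0, and -0.83 for DNA replication genes, with 2 of 47 above 0. In each list 12 genes were 2-fold lower, and both medians lay below all random lists. MCM10 (-2.07), MAD2L1 (-1.56), CDK1 (-1.55) and DSCC1 (-1.53) were among the lowest. E2-repressed genes had a median of 0.48, above all random lists; ID1 (2.63), CYP1A1 (18.1 and 107 FPKM), BCAS1 (2.13) and SMAD6 (1.97) were higher, and TXNIP (-1.45) and CRABP2 (-1.37) were 2-fold lower. Ribosomal protein genes (median 0.52, above all random lists, RPL11 at 1.15 and RPS8 at 1.03) and basal markers (0.39, percentile 99.9, ANXA1 at 1.33 and KRT15 at -2.04) were higher as lists. Luminal regulators had a median of 0.15 (percentile 92.9) and a mean of -0.01; XBP1 (-2.35) alone was 2-fold lower, and KRT8 was higher by 0.83. Unfolded protein genes had a median of -0.32 (percentile 0.17; DDIT4 at 1.72, PHGDH at 1.46 and DNAJB9 at -1.13). p53 targets had one of 0.26 (percentile 99.6; BTG2 at 1.53).

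Medians of the remaining lists with E2 were inside the central 95% of random lists. They were 0.16 for immediate early genes (percentile 92.9; CTGF at 1.97, JUN at 1.03, NR4A1 at -1.19 and KLF2 at -1.11), -0.07 for mesenchymal markers (percentile 34.6; COL5A1 at 2.08 and VIM at -1.58) and -0.06 for histone genes (percentile 31.4). For ribosome biogenesis the median was 0.08 (percentile 80.6), for oxidative phosphorylation 0.01 (percentile 57.4), for hypoxia 0.15 (percentile 91.9; NDRG1 at 1.84) and for cholesterol synthesis 0.03 (percentile 63.1; DHCR24 at 1.34 and IDI1 at -1.15). For matrix metalloproteinase genes it was 0.26 (percentile 90.7; MMP9 at 1.14 and MMP16 at -1.06) and for housekeeping genes -0.07 (percentile 25.6; B2M at -1.62). At the ends among genes outside the lists with a mean of at least 5 FPKM lay FXYD4 (-5.67), CXorf61 (-5.27, 42.7 and 0.132 FPKM), ENTPD8 (-4.13), CEACAM5 (-4.06), ACTG2 (-3.84) and CXCL17 (-3.54), and at the other end WNT6 (3.90), KRT4 (3.63), GABRP (3.41), AKR1C2 (2.91), BTG3 (2.90), GABARAPL1 (2.74) and GOLM1 (2.72). CELSR3 (6.33) rests on 1 library, and so does the size of the UBA7 difference (-5.08). UBA7 was also lower without E2 (-1.685, 3.91 and 0.527 FPKM). In all, 401 rows were higher and 601 lower, and 366 and 578 without small RNA rows.

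**Figure D3:**
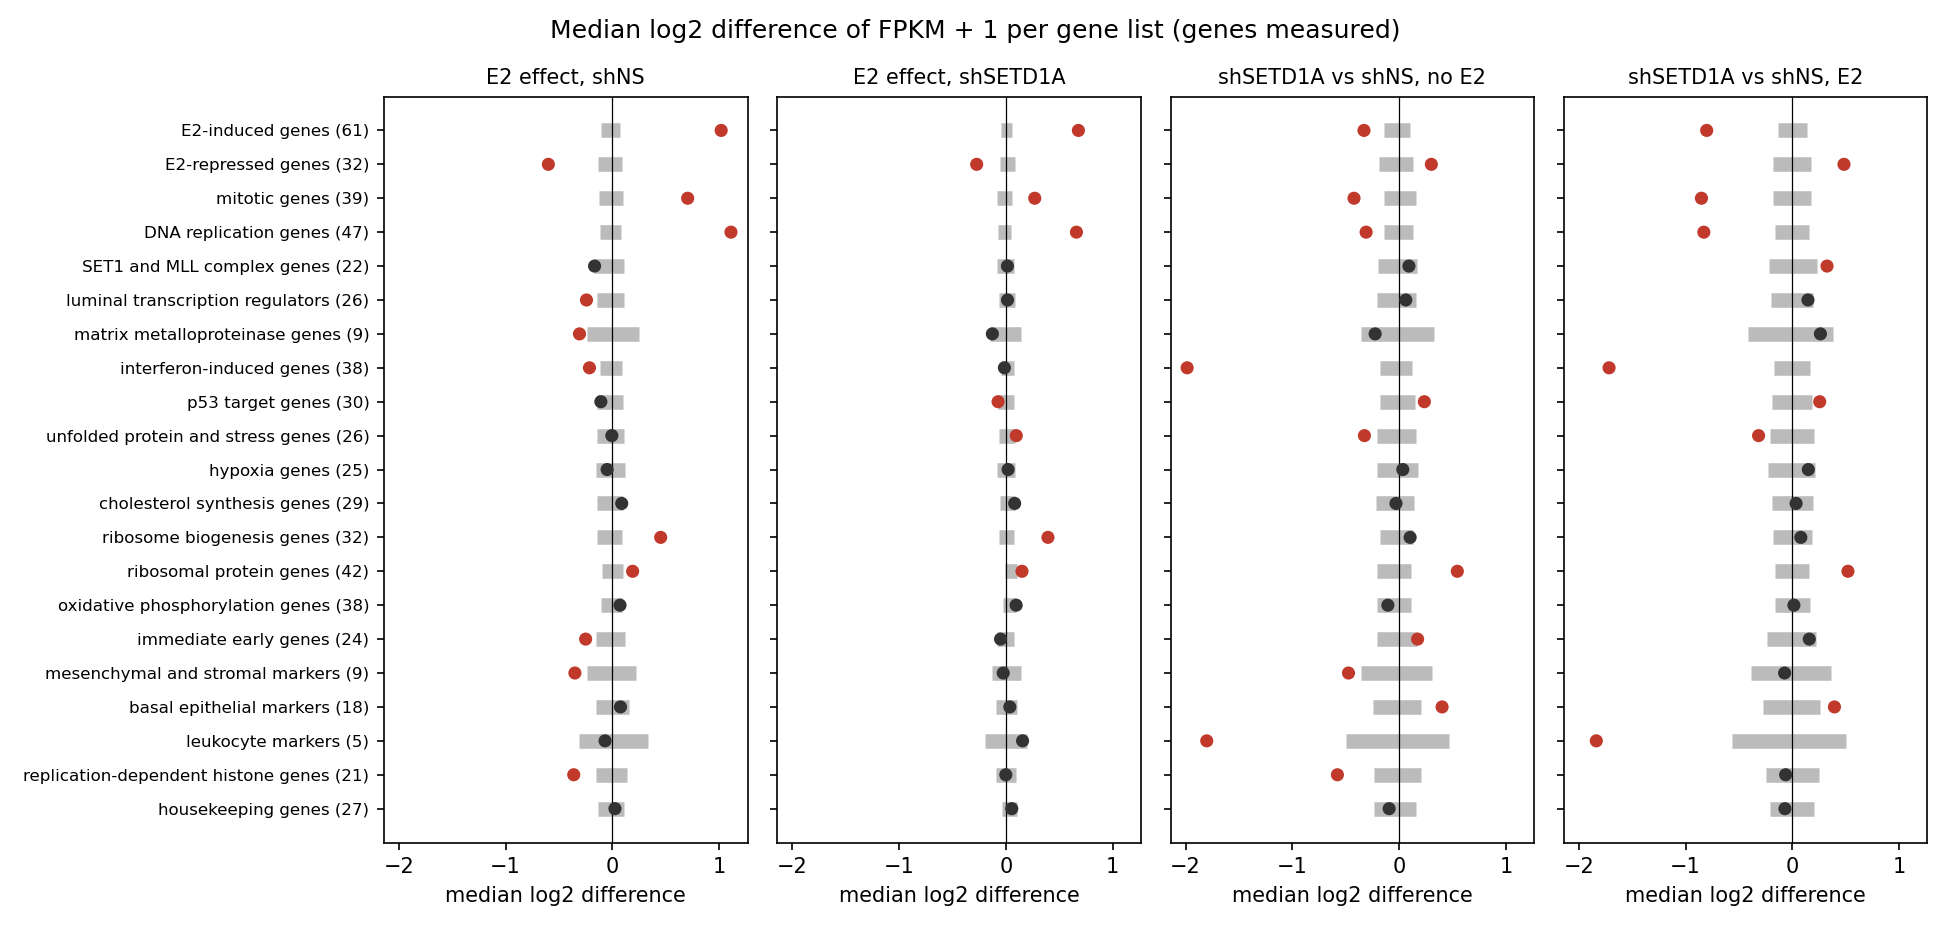
Median log2 difference of FPKM + 1 of each list (number of measured genes in brackets) in 4 comparisons. Points are list medians, grey bars the central 95% of 10000 random lists of the same size and level, and red points lie outside it; interferon-induced genes stand at -1.99 and -1.72 between the shRNAs and DNA replication genes at 1.11 and 0.66 with E2.

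The 2 E2 comparisons share no library, and neither do the 2 comparisons of the shRNAs. Without small RNA rows, 40 genes were at least 2-fold higher with E2 under both shRNAs, against 0.763 for independent lists of that size. GREB1, NPY1R, MYB, CALCR and STC2 led by the smaller of their differences (3.13, 2.35, 2.13, 2.05 and 1.84). The 1 gene 2-fold lower under both was MME (-1.05), a cell surface peptidase. Between the shRNAs, 235 genes were higher in the libraries labelled shSETD1A both without and with E2, against 9.22 for independent lists, and 363 were lower in both, against 25.7. WNT6 (3.90), KRT4 (3.63), GABRP (3.29), ADD3 and AKR1C2 (2.91) led the first. FXYD4 (-5.67), CXorf61, ASCL1 (-4.11), CEACAM5 (-4.06) and ACTG2 (-3.84) led the second, of which 30 are on the interferon list. With small RNA rows the counts were 45 and 4 for E2, and 241 and 369 for the shRNAs. Across genes, Pearson's r was 0.53 for the E2 differences and 0.86 for the shRNA differences without small RNA rows, and 0.17 and 0.62 with them. Genes are not independent replicates, and the labels do not say whether the libraries of 1 shRNA came from separate cultures.

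**Figure D4:**
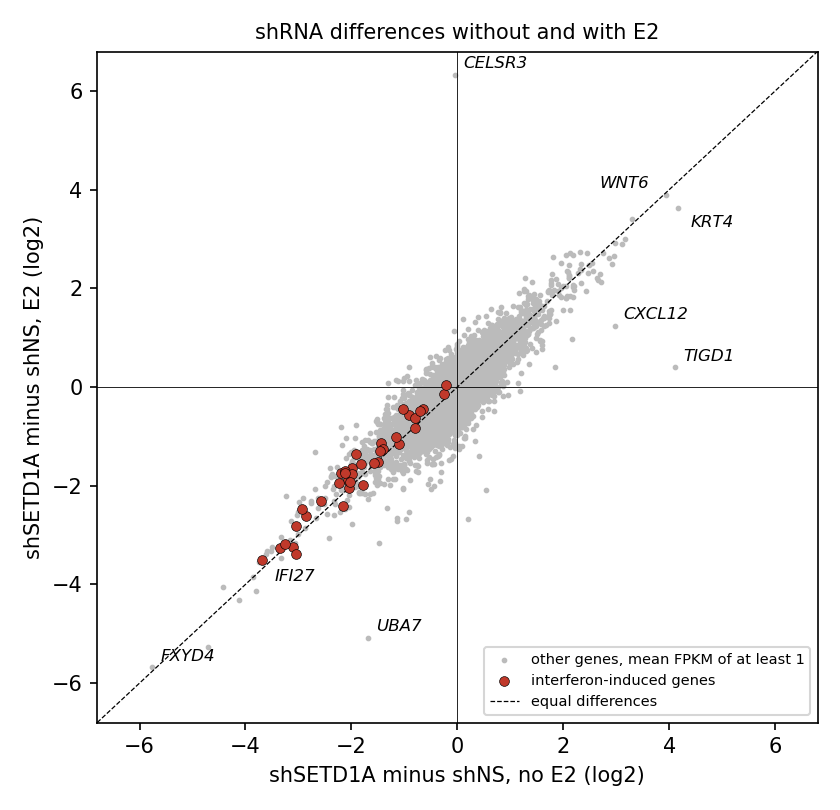
Difference between the library labelled shSETD1A and shNS (log2 of FPKM + 1) without E2 (x axis) and with E2 (y axis), 1 point per gene other than small RNA rows; red points are the 38 measured interferon-induced genes and the dashed line marks equal differences. Their medians are -1.99 and -1.72, and CELSR3, TIGD1 and UBA7 lie apart through 1 library each.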

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

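The comparison that picked out HIF1A-AS2 was chosen after seeing the data. HIF1A-AS2, a gene antisense to HIF1A, had E2 differences of opposite sign under the 2 shRNAs: 2.09 in shNS (4.79 to 23.7 FPKM) and -0.77 in the library labelled shSETD1A (5.62 to 2.87 FPKM). Among the named genes other than small RNA rows, it was the 1 whose 2 differences had opposite signs and each exceeded 1.5-fold. The difference between them was not tested, since each group is 1 library. Most of it comes from the single value of 23.7 FPKM in shNS with E2. HIF1A itself stood at 83.0 and 90.4 FPKM in shNS and at 48.5 and 54.6 FPKM in the libraries labelled shSETD1A, without and with E2. How strand was counted is not given in the sources used here, so fragments of the 2 genes cannot be kept apart with certainty. No biological explanation was tested.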

How the results depend on the processing

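Leaving out small RNA rows was chosen after seeing the data; the other settings were fixed before the data were examined. No paired analysis was possible because each group is 1 library and the labels carry no replicate numbers, and no library could be left out. Of 4355 values under alternatives, 4189 kept their value within the limits set and 166 moved, and 0 changed sign among those called. The limits were 1.5 times for a count and 1 log2 unit for a gene. For a median or level the limit was the spread of random lists or of counting. A gene's difference cannot change with the filter or when other rows are left out, so part of the 4189 was fixed in advance. Of 28 main results, 18 moved with a pseudocount of 0.1, 22 with 5 and 13 with a mean of at least 5 FPKM. Another 6 moved without small RNA rows and 1 with upper-quartile scaling. The median of all genes shifted by at most 0.05 (log2) under either scaling, and median-of-ratios scaling and no filter moved no count or list median given here as a main result. Calls follow the pseudocount and filter by construction, since both act on low genes. With a pseudocount of 0.1, E2 in shNS gave 306 higher and 146 lower, E2 in shSETD1A 140 and 48, shSETD1A against shNS with E2 606 higher, and the difference of E2 differences 119 higher and 159 lower. Shared calls were then 84 higher and 13 lower for E2 and 379 higher for the shRNAs. The E2-induced medians were 1.14 and 0.86 with E2 (ratio 0.757) and -0.42 and -0.99 between the shRNAs, and the replication medians 1.19, 0.73 and, between the shRNAs with E2, -0.92. With a pseudocount of 5, E2 in shNS gave 88 higher and 30 lower and E2 in shSETD1A 50 higher. Between the shRNAs there were 154 higher and 256 lower without E2, and 178 and 263 with E2. The difference of E2 differences gave 40 and 44. Shared calls were 17 higher for E2, and 106 higher and 168 lower for the shRNAs. The E2-induced medians were 0.82, 0.55, -0.20 and -0.54, and -0.29 for the difference. The replication medians were 0.83, 0.41 and -0.60, and the interferon medians -1.58 and -1.37. With a mean of at least 5 FPKM, E2 in shNS gave 123 higher, E2 in shSETD1A 54 higher and 16 lower, and the shRNAs 207 higher without and 260 higher with E2. The difference of E2 differences gave 31 and 53, and shared calls were 1 lower for E2 and 158 higher for the shRNAs. The E2-induced median was 0.93 in shNS, -0.47 between the shRNAs without E2 and -0.17 for the difference, with a ratio of 0.731. Without small RNA rows, E2 in shNS gave 42 lower, E2 in shSETD1A 54 higher and 4 lower, the difference 21 and 56, and 1 gene was lower with E2 under both shRNAs. With upper-quartile scaling the E2-induced median of the difference was -0.28. Where no cause is given by construction, the cause was not tested. Depth is known only approximately, and with 1 library per group no setting replaces a replicate.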

Other observations

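The tests of explanations below were chosen after the results were seen, although the 2 other scalings they use were fixed before, and so were the 5 gene groups that follow, which hold genes already seen to differ, so their counts and medians only describe these genes. Of 17 measured genes of antigen presentation, 14 were at least 2-fold lower without E2 and 13 with E2 in the libraries labelled shSETD1A, in which SETD1A was not lower, with medians of -1.46 and -1.62. B2M, the class I light chain, stood at 1004 and 1021 FPKM in shNS and at 366 and 331 FPKM in shSETD1A. TAP1 (-2.12 and -1.73), PSMB9 (-2.03 and -1.92) and HLA-DRB1 (-2.05 and -2.43) were also lower. TAP1 and PSMB9 are on the interferon list too, CD74 and HLA-DRA on the leukocyte list, and B2M is on the housekeeping list.

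Of the targets of the aryl hydrocarbon receptor, 4 of 7 were 2-fold higher in the libraries labelled shSETD1A in each comparison (medians 1.29 and 1.66). CYP1A1 stood at 20.6 and 18.1 FPKM in shNS against 125 and 107 FPKM, and CYP1B1 at 18.2 and 23.0 against 102 and 91.3 FPKM. ALDH3A1 and ALDH3B1 were the other two, and AHRR was counted from a row it shares with PDCD6. Among aldo-keto reductase and NRF2 genes (medians 0.46 and 0.39), AKR1C2 stood at 42.7 and 41.2 against 344 and 316 FPKM, while HMOX1 (-0.90 and -0.52) and TXNRD1 (-0.37 and -0.28) were lower. YAP and TEAD targets had medians of 0.51 and 0.85, with CTGF, ANKRD1, AMOTL1, AMOT, TGFB2 and F3 past 2-fold in both. BMP and ID genes had medians of 0.80 and 1.09; ID1 (1.80 and 2.63), SMAD6 (1.82 and 1.97) and BMP4 (1.41 and 1.78) led. In these 4 groups, 4 BMP and ID genes, CYP1A1 and TGFB2 are also on the E2-repressed list. With E2 in shNS, the groups' medians were -0.17 for antigen presentation, -0.18 for aryl hydrocarbon receptor targets, -0.39 for YAP and TEAD targets, -0.09 for aldo-keto reductase genes and -0.41 for BMP and ID genes.

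SETD1A was not lower in the libraries labelled shSETD1A. Scaling by the authors is argued against only if most genes are alike between libraries, which the 2 other scalings take as given. The smallest log2 difference of SETD1A under them was 0.22, still above 0. They changed the values little (factors of 0.986 to 1.02) and would miss a shift shared by most genes. An exchange of the 2 shRNA labels cannot be told apart from unexchanged labels: SETD1A was higher in both libraries labelled shSETD1A, but the lower of its percentiles among genes of like level was 72.6, so its difference is ordinary for these libraries. A knockdown of the protein or one lost by the time of sampling stays open and was not tested.

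Very large values beside a 0 in another library sat mostly on small RNA genes. Of 44 rows listed at 0 in 1 library and at 20 FPKM or more in another, 43 were small RNA rows (97.7%, against 0.775% of the rows compared), and the other was CXorf61. A few fragments on very short genes may therefore account for them. Not all of the 44 rows were high in a single library. SNORD104 stood at 757 and 764 FPKM in shNS and was listed at 0 in both libraries labelled shSETD1A. MIR25 was listed at 0 in both shNS libraries and stood at 396 and 1006 FPKM in those labelled shSETD1A. Of longer genes, 3 had 1 library over 8-fold above the others, and 3 of 3 (TIGD1, CELSR3 and UBA7) overlap a miRNA gene (MIR5001, MIR4793 and MIR5193), against 2.41% of longer genes compared. None of these miRNAs has a row of its own, so the same short-gene inflation could have entered the longer gene's value. No biological explanation was tested.

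Interferon-induced genes were lower in both libraries labelled shSETD1A, and leukocytes in the shNS cultures are argued against, since the higher median of the 20 genes of the fixed leukocyte list there was 0.1025 FPKM and PTPRC, found in all leukocytes, was at most 0.052 FPKM. The list's 5 genes at 1 FPKM or more were LCP1 (129 and 123 FPKM in shNS), CD74 (11.8 and 10.6), CORO1A (8.16 and 8.20), HLA-DRA (6.22 and 8.14) and CD68 (1.92 and 1.74). Scaling is argued against too, as the median nearest 0 under 2 other scalings was -1.71. These scalings changed the values little (factors of 0.986 to 1.02) and take most genes as alike. They would miss a shift shared by most genes. Cell populations that had diverged before the experiment cannot be told apart from an effect of the shRNA, since each shRNA has 1 library per condition: 10 genes outside the list, WNT6, KRT4 and CXADR among them, were at 5 FPKM or more in both libraries of 1 shRNA and under 0.5 in both of the other, and 0 genes were so switched by E2. An effect of the shRNA, through SETD1A or not, stays open and was not tested; DHX58 and RTP4, 2 of the 10, are known to respond to interferon.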
